A study of Mus musculus with 90 samples.

How the data were processed

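Gene expression was measured in lung, liver, spleen, kidney cortex and kidney medulla of Balb/c mice 24 h after intravenous injection of astatine-211, an alpha-emitting radionuclide. Each tissue had 6 groups, at injected activities of 0, 0.064, 0.64, 1.8, 14 and 42 kBq, with 3 arrays per group, which made 90 arrays in 30 groups. The arrays were single-colour Illumina mouse bead arrays hybridised with biotin-labelled total RNA.

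The deposited unnormalised table held an intensity for each probe and array, on a linear scale, neither background-subtracted nor normalised. Beside each intensity the deposited table held a detection p-value, the p-value that the probe did not exceed the background of its array. The value table that the authors deposited held a processed intensity on a linear scale. Its columns had medians from 117.5 to 117.9 on 60 arrays and from 164.8 to 165.5 on the other 30, and the rank correlation of each column with the unnormalised intensity of its array was at least 0.9992. How the authors normalised it was not stated.

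The deposited values also parted the arrays. On the 60 arrays of 0, 1.8, 14 and 42 kBq, a median of 99.53% of the deposited values were multiples of 1 divided by 80, within a tolerance of 0.01 of a step. On the 30 arrays of 0.064 and 0.64 kBq, a median of 99.32% were multiples of 1 divided by 33. The deposited values thus lay on 2 different grids, and the arrays are called set 1 (60 arrays) and set 2 (30 arrays) below. All 0 kBq arrays belonged to set 1, so array set and activity cannot be told apart in any comparison of 0.064 or 0.64 kBq with another activity. The comparisons of 1.8, 14 and 42 kBq with 0 kBq, and of 0.64 kBq with 0.064 kBq, each lay within 1 set. The last of these was added after the sets had been seen.

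The array held 25697 probes. Of these, 23978 had 1 gene symbol, 0 had several and 1719 had none. The Entrez identifiers of 23962 probes were found in the reference table, through which old symbols were updated. Gene positions and a genome build were not used. Of 763 gene names in 44 gene lists, 758 matched a gene.

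Background was corrected by normal-exponential convolution with the background estimated from the detection p-values (limma 3.58.1, R 4.3.3), an offset of 16 was added, and log2 intensities were quantile normalised within each tissue. A probe was tested in a tissue when its detection p was under 0.05 on at least 3 arrays. This left 16048 probes in lung, 13673 in liver, 15310 in spleen, 15063 in kidney cortex and 15298 in kidney medulla. For the tests between tissues the 90 arrays were normalised together, with 18463 probes. Probes detected per array numbered between 11229 and 14456. The median unnormalised intensity of an array lay between 86.08 and 151.7 in set 1 and between 123.9 and 196 in set 2. The number of arrays limits the precision.

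In each tissue limma fitted 1 mean per group over all 18 arrays (12 residual degrees of freedom, moderated variances with an intensity trend). Tests were two-sided, with Benjamini-Hochberg adjustment over the probes of a contrast, and a probe was called at an adjusted p under 0.05. All adjusted p-values for genes are from limma. The contrasts were each activity against 0 kBq, the mean of the 5 injected groups against 0 kBq, and the slope over log10 activity. Whether the response differed between kidney cortex and kidney medulla, or among the 5 tissues, was tested as an interaction in 1 fit of all arrays. Gene lists were tested with camera from limma, which compares a list with all other genes, at a preset inter-gene correlation of 0.01, for lists with at least 5 measured genes and 1 probe per gene. List p-values were adjusted over all lists and activities of a tissue. Each was repeated with an estimated inter-gene correlation. The p-values measure only the spread between these arrays.

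Where a probe was undetected on all arrays of the dimmer group, the fold is given as a lower bound, "at least", against the detection limit of those arrays. Where a gene had several probes, the probe with the highest mean over the 18 arrays of the tissue is reported. The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. By that rule the named genes of a tissue were the 10 called at the most activities, the 2 largest rises and falls per activity with values that did not overlap the controls, the 3 largest in each direction for the pooled contrast and the slope, up to 4 called members per list, 9 genes of the p53 response and the circadian clock whatever their values, and the 5 largest differences in each direction between tissues. Eif2s3y, Xist and the islet genes lie outside the rule and were added after the data had been seen.

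The procedure was tested on simulated data, in which 50 probes per step were shifted at 42 kBq in each tissue. Of the probes shifted by 1 on the log2 scale, 74% were called in lung, 90% in liver, 84% in spleen, 90% in kidney cortex and 80% in kidney medulla. Of those shifted by 0.5, between 14% and 32% were called. Among the unshifted probes 5, 5, 7, 4 and 13 were called in the 5 tissues in the same order. A simulated shift of 0.25 in the DNA repair list of spleen was called with adjusted p = 2.75e-08 (camera), and 0 of 174 other pairs of list and activity were called. The simulated probes varied independently of each other, so this step could not show false list calls from genes that vary together. Regrouped real spleen arrays gave up to 58 called pairs.

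The alternatives were no background correction, normalisation over all 90 arrays, no filter on dim probes, the deposited value table, the replicate number as a block, a stricter threshold, the 6 arrays of a comparison alone, an estimated inter-gene correlation, and each array left out in turn. Fits without the 0.064 and 0.64 kBq arrays, or with 1.8, 14 and 42 kBq alone, were added after the data had been seen. For the spread within groups, each list was set against 20 random gene sets of its size, drawn from genes with mean levels in the same decile. The files named no chip for any array, so chip could not be used as a block.

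The labels number the arrays of every group from 1 to 3 but do not state what a number stands for. In 5 of 30 comparisons all 3 pairs of same-numbered arrays deviated together from their group means (correlation across probes over 0.1). These were 0.64 against 0.064 kBq in lung and kidney cortex, 14 and 42 against 0 kBq in spleen, and 1.8 against 0 kBq in kidney cortex.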

Results

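The data were expression levels in 5 tissues of mice 24 h after injection of astatine-211, at 5 activities and in 0 kBq controls, with 3 arrays per group. Levels are log2 intensities, given with SD and n = 3 arrays. The study asked how tissues respond in transcription to low absorbed doses. On each array between 11229 and 14456 probes were detected. The median over the genes of the alveolar epithelium list was between 12.46 and 13.19 on lung arrays, that of the hepatocyte list between 13.28 and 13.92 on liver arrays, and that of the B cell list between 8.72 and 9.88 on spleen arrays. Marker lists did not tell the kidney zones apart: the proximal tubule list was between 11.12 and 12.92 in cortex and between 12.25 and 12.93 in medulla, and the collecting duct list between 7.85 and 8.94 and between 8.34 and 9.35. Without the 0.064 and 0.64 kBq arrays, a fit added after the data had been seen, 14 of the 15 counts of calls at 1.8, 14 and 42 kBq were over 1.5 times higher. The comparisons within 1 array set come first.

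**Figure D1:**
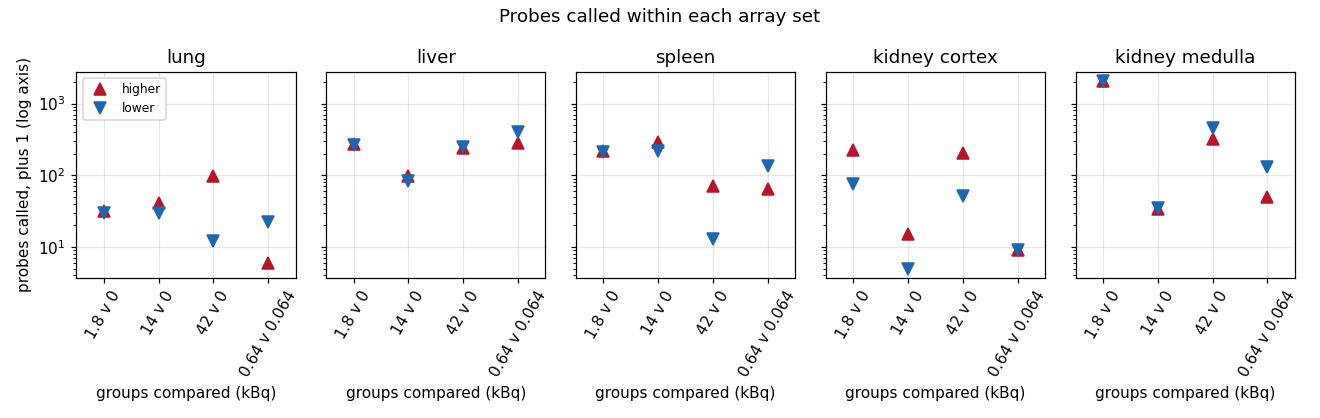
Probes called higher (triangles up) or lower (triangles down) at an adjusted p under 0.05 in the comparisons within an array set, by tissue, on a log axis after adding 1. Kidney medulla at 1.8 kBq had the most, with 2046 higher and 2029 lower.

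In lung at 42 kBq, airway secretory genes and striated muscle genes rose. Bpifa1, a secreted airway defence protein, rose from 4.68 ± 0.17 (SD, n = 3), undetected, to 11.54 ± 0.21 (SD, n = 3), at least 89.3-fold (adjusted p = 1.03e-05, limma). Scgb3a1, a secretoglobin, rose by 4.86 ± 0.64 (SE), or 29-fold, and Bpifb1 rose 13.1-fold. Reg3g, an antimicrobial lectin, rose at least 13.3-fold. All 9 measured genes of the cardiac muscle list rose (list adjusted p = 5.14e-42, adjusted p = 0.0117 with an estimated correlation). Among them Nppa, atrial natriuretic peptide, rose at least 77.8-fold and Myl7, an atrial myosin light chain, 5.04-fold. Of 11 skeletal muscle genes 5 rose over all probes and 6 when adjusted over the list alone (adjusted p = 5.03e-13, adjusted p = 0.0606 with an estimated correlation), Acta1 at least 20.6-fold. Of the 10 genes of the airway epithelium list 4 rose, with the same 4 when counted as adjusted over the list alone (adjusted p = 7.29e-11, adjusted p = 0.0221 with an estimated correlation).

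The lung at 42 kBq also had higher Angptl4, an inhibitor of lipoprotein lipase, at 10.23 ± 0.09 against 9.15 ± 0.09 (SD, n = 3), 2.12-fold (adjusted p = 8.02e-07). Per1, a clock gene that glucocorticoids induce, rose 2.03-fold and Usp2 1.66-fold. Of 10 glucocorticoid and fasting responsive genes 1 rose over all probes and 5 when adjusted over the list alone (adjusted p = 1.96e-08, adjusted p = 0.0117 with an estimated correlation). The interferon-induced chemokine Cxcl9 fell by 2.01 on the log2 scale, the heat shock genes Hspa1a and Hsph1 fell by 0.83 and 0.67, and Fcrls, an Fc receptor-like gene, fell by 0.98. The p53 target Cdkn1a had a change of 0.50 with adjusted p = 0.28. In all, 98 probes rose and 11 fell of 16048 tested. With 1 of the 6 arrays left out 64 to 81 were called, the fewest without array 1 or 2 of 42 kBq, and 72 without array 3 of 0 kBq.

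In lung at 14 kBq the same airway genes were higher: Scgb3a1 11-fold, Bpifb1 10.2-fold and Bpifa1 at least 14.5-fold. Neutrophil granule genes fell, Camp by 2.78 and Ngp by 2.48. In that list 4 of 13 genes fell over all probes and 8 when adjusted over the list alone (adjusted p = 2.69e-09, adjusted p = 0.195 with an estimated correlation). Cxcl9 fell by 3.19 and Cxcl10 by 1.39. Oas1g, an interferon-induced gene, went from 7.67 ± 0.03 to undetected, at least 6.25-fold lower (adjusted p = 0.0174). Hsph1 fell by 1.13. In all, 40 probes rose and 29 fell. Leaving out array 1 of 0 kBq gave 100 calls, and leaving out any other of the 6 arrays 20 to 33.

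In lung at 1.8 kBq immediate early genes rose: 6 of 16 over all probes and 10 when adjusted over the list alone (adjusted p = 3.1e-13, adjusted p = 0.00148 with an estimated correlation). Egr1 rose 2.43-fold and Csrnp1 2.14-fold. Cardiac muscle genes moved opposite to 42 kBq. Of 9 genes 3 fell over all probes and 6 when adjusted over the list alone (adjusted p = 2.61e-09, adjusted p = 0.266 with an estimated correlation), with Mybphl lower by a log2 change of -1.53. Cxcl9, Hspa1a and Hsph1 fell by 2.02, 1.26 and 1.03. Bpifa1 was 4.66 ± 0.42 against 4.68 ± 0.17 (SD, n = 3). In all, 31 probes rose and 29 fell. Leaving out array 1 of 0 kBq gave 140 calls, leaving out any other of the 6 arrays 9 to 38 (9 without array 2 of 0 kBq), and leaving out the 0.064 and 0.64 kBq arrays 615.

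**Figure D2:**
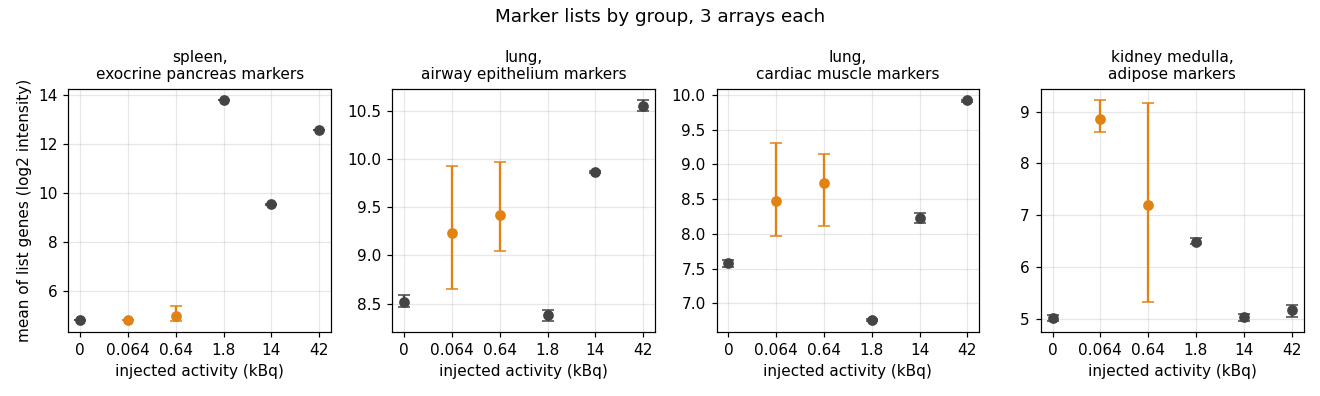
Mean level of 4 marker lists (log2 intensity) by group. Points are group means, bars run from the lowest to the highest of 3 arrays, dark points are set 1 and light points set 2. The exocrine pancreas list in spleen was 4.84 at 0 kBq and 13.82 at 1.8 kBq.

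In liver at 1.8 kBq the inflammatory cytokine and adhesion list was higher and the lipogenesis list lower. Of 11 inflammatory genes 3 rose over all probes and 4 when adjusted over the list alone (adjusted p = 5.61e-05, adjusted p = 0.0805 with an estimated correlation). The metallothionein and antioxidant list was not called (adjusted p = 0.29), with 2 of 19 genes risen. Mt1, a metal-binding stress protein, rose from 10.98 ± 0.02 to 14.42 ± 0.05 (SD, n = 3), 10.8-fold (adjusted p = 5.94e-11). Egr1 rose 7.77-fold, the chemokine Cxcl1 5-fold, Rgs16 4.67-fold and Fgf21 2.11-fold. Of 13 lipogenesis genes 5 fell over all probes and 8 when adjusted over the list alone (adjusted p = 8.04e-05, adjusted p = 0.0859 with an estimated correlation). Srebf1, a regulator of lipid synthesis, fell by 1.39, and the thyroid-responsive genes Thrsp and Dio1 fell by 1.19 and 1.62. Of 13 heat shock genes 4 fell over all probes and 10 when adjusted over the list alone (adjusted p = 1.99e-08, adjusted p = 0.0588 with an estimated correlation), Hsph1 by 1.45. Dmbt1, a mucosal scavenger receptor protein, went from 9.88 ± 0.08 to undetected, at least 28.1-fold lower. In all, 270 probes rose and 266 fell of 13673. With any 1 of the 6 arrays left out 194 to 274 were called, and without the 0.064 and 0.64 kBq arrays 1876.

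In liver at 14 and 42 kBq genes that respond to glucocorticoids and fasting rose. At 14 kBq 4 of 13 rose over all probes and 7 when adjusted over the list alone (adjusted p = 3.5e-09, adjusted p = 0.00462 with an estimated correlation). At 42 kBq 7 of 13 rose over all probes and 8 when adjusted over the list alone (adjusted p = 2.88e-07, adjusted p = 0.00943 with an estimated correlation). G6pc, of gluconeogenesis, rose 2.73-fold at 14 kBq and 1.67-fold at 42 kBq. Per1 rose 2.75-fold and 3.32-fold, Rgs16 6.04-fold and 6.56-fold, and Mt1 4.15-fold and 6.09-fold. At 42 kBq Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose 2.6-fold, Usp2 3.17-fold, and the clock gene Arntl went from 6.01 ± 0.27 to undetected, at least 2-fold lower (adjusted p = 0.000941).

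Endoplasmic reticulum stress genes fell in liver at 42 kBq, 5 of 15 over all probes and 7 when adjusted over the list alone (adjusted p = 0.000348, adjusted p = 0.0805 with an estimated correlation), and Hspa5, the main chaperone there, fell by 1.49. Hsph1 fell by 1.81 at 14 kBq and 1.77 at 42 kBq, and the macrophage chemokine Ccl8 fell by 2.18 at 14 kBq and was at least 4.02-fold lower at 42 kBq. Neutrophil and granule genes were lower at 14 kBq (8 of 13 adjusted over the list alone, 1 over all probes, adjusted p = 2.26e-05, adjusted p = 0.53 with an estimated correlation). They were higher at 42 kBq (7 adjusted over the list alone, 4 over all probes, adjusted p = 1.99e-08, adjusted p = 0.314 with an estimated correlation). At 14 kBq 97 probes rose and 81 fell, and at 42 kBq 240 rose and 243 fell. With 1 array left out the calls numbered 67 to 98 at 14 kBq and 237 to 309 at 42 kBq.

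In spleen, digestive enzyme genes of the exocrine pancreas were the largest rises at 1.8, 14 and 42 kBq. All 20 measured genes of that list rose at each of these activities, over all probes and when adjusted over the list alone (adjusted p = 9.58e-155, 3.55e-106 and 2.77e-226, and adjusted p = 1.89e-06, 1.09e-05 and 3.93e-07 with an estimated correlation). Clps, pancreatic colipase, was undetected at 0 kBq (4.47 ± 0.10) and reached 14.76 ± 0.03 at 1.8 kBq, 10.55 ± 0.01 at 14 kBq and 13.77 ± 0.05 at 42 kBq (SD, n = 3). These were at least 848-fold, 45.8-fold and 425-fold higher. Amy2a5, pancreatic amylase, was at least 709-fold, 70.2-fold and 435-fold higher. The mean of the list was 4.84 at 0 and 0.064 kBq and 5.0 at 0.64 kBq. Pancreatic tissue taken with the spleen may account for these rises, which was not settled, so they are not read as a response of spleen cells.

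Beside these, proliferation genes fell in spleen. The mean of the exocrine pancreas list was 13.82, 9.56 and 12.6 at 1.8, 14 and 42 kBq. If pancreatic tissue was present, its RNA would make up part of these samples. Whether that altered the measured levels of other genes was not tested. At 14 kBq 7 of 22 fell over all probes and 14 when adjusted over the list alone (adjusted p = 4.35e-12, adjusted p = 0.132 with an estimated correlation). At 1.8 kBq 5 fell over all probes and 10 when adjusted over the list alone (adjusted p = 1.21e-07, adjusted p = 0.256 with an estimated correlation). Top2a, a topoisomerase of dividing cells, fell by 0.72 and 0.73 at 1.8 and 14 kBq, and at 42 kBq its change was -0.34 with adjusted p = 0.54. The DNA repair list was lower at 14 kBq with 1 of 22 genes called over all probes and 3 lower and 1 higher when adjusted over the list alone (adjusted p = 0.00132, adjusted p = 0.0558 with an estimated correlation). Angptl4 rose 2.18-fold, 2.58-fold and 2.18-fold at the 3 activities and the matrix gene Matn4 fell by 2.21, 2.09 and 2.32. The glucocorticoid-induced Tsc22d3 rose 1.82-fold at 14 kBq, where Oas1g was at least 7.17-fold lower and Isg15 fell by 0.92.

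In all, 220 spleen probes rose and 209 fell at 1.8 kBq, 290 and 215 at 14 kBq, and 69 and 12 at 42 kBq, pancreas genes included. With 1 of the 6 arrays left out 207 to 287 were called at 1.8 kBq and 129 to 244 at 14 kBq, the fewest in both without array 2 of 0 kBq. At 1.8 and 42 kBq 65 probes rose in both, where independent lists would share 0.992. These comparisons share the control arrays, and with unchanged simulated groups the mean number called in both was 0. Their changes had a covariance of 0.212 across probes against 0.0203 simulated. Part of the excess may come from the shared controls, and the simulated probes varied independently. The 20 genes of the exocrine pancreas list rose at both activities and are among the 65 probes. The overlap and the covariance without them were not computed.

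In kidney cortex at 1.8 kBq tubular injury and acute phase genes rose. Havcr1, kidney injury molecule 1, rose from 6.48 ± 0.21 to 10.20 ± 0.38 (SD, n = 3), 13.1-fold (adjusted p = 0.00197). In medulla the Havcr1 level at 0 kBq was higher than this. Whether the cortex samples of each group held the same part of the kidney was not tested. Lcn2, an injury marker of tubules, rose 12.1-fold, Cxcl1 10.6-fold, Timp1 4.66-fold and the fibrinogen gene Fga 7.74-fold. Of 11 tubular injury genes 7 rose over all probes and 10 when adjusted over the list alone (adjusted p = 6.49e-17, adjusted p = 0.000132 with an estimated correlation). Of 10 inflammatory cytokine and adhesion genes 4 rose over all probes and 6 when adjusted over the list alone (adjusted p = 2.02e-06, adjusted p = 0.0407 with an estimated correlation). Of 12 acute phase genes 5 rose over all probes and 7 when adjusted over the list alone (adjusted p = 7.68e-09, adjusted p = 0.0998 with an estimated correlation). The p53 target Cdkn1a rose 2.16-fold. In the cholesterol synthesis list 1 of 14 fell over all probes and 8 when adjusted over the list alone (adjusted p = 4.87e-06, adjusted p = 0.0483 with an estimated correlation). In all, 226 probes rose and 75 fell of 15063, and with 1 array left out 103 to 192 were called.

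In kidney cortex at 42 kBq Spink6 rose 21.3-fold, Serpina1f 21-fold, the transporter Slc22a13 12.5-fold, and Kap, an androgen-regulated gene of the proximal tubule, from 10.02 ± 0.37 to 13.50 ± 0.42 (SD, n = 3), 11.2-fold (adjusted p = 0.0338). Napsa, an aspartic protease, rose 5.74-fold, Angptl4 3.43-fold and Per1 2.99-fold. Havcr1 rose 6.98-fold, and Fcrls fell by 1.16. The proximal tubule list was not called (adjusted p = 0.919), with 1 of 11 genes risen. At 14 kBq Slc22a13 rose 4.53-fold, Napsa 2.57-fold, Angptl4 3.03-fold, Per1 2.78-fold and the cold-inducible gene Cirbp 2.07-fold, and Kap had a change of 1.95 with adjusted p = 0.477. There were 205 rises and 51 falls at 42 kBq, and 14 and 4 at 14 kBq. With 1 array left out 137 to 168 were called at 42 kBq and 2 to 5 at 14 kBq.

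In kidney medulla at 1.8 kBq injury and immediate early genes rose, and the oxidative phosphorylation and proximal tubule lists were lower. Lcn2 rose from 7.19 ± 0.16 to 10.47 ± 0.04 (SD, n = 3), 9.69-fold (adjusted p = 6.65e-12), Cxcl1 7.2-fold, Fos 3.3-fold and Cdkn1a 1.96-fold. Of 15 immediate early genes 11 rose, with 11 also when adjusted over the list alone (adjusted p = 1.7e-05, adjusted p = 0.0868 with an estimated correlation). Of 12 tubular injury genes 8 rose and 1 fell over all probes, and 10 rose and 1 fell when adjusted over the list alone (adjusted p = 3.82e-05, adjusted p = 0.076 with an estimated correlation). Of 34 oxidative phosphorylation genes 13 fell and 1 rose over all probes, and 14 fell and 1 rose when adjusted over the list alone (adjusted p = 0.00016, adjusted p = 0.076 with an estimated correlation). Of 11 proximal tubule genes 6 fell and 1 rose over all probes, with the same counts when adjusted over the list alone (adjusted p = 0.0167, adjusted p = 0.279 with an estimated correlation), and Kap fell by 1.25. Havcr1 fell by 0.68, from 11.63 ± 0.10 to 10.94 ± 0.03 (SD, n = 3). The fat cell gene Adipoq rose 7.59-fold, and whether fat taken with the medulla accounts for it was not tested. In all, 2046 probes rose and 2029 fell of 15298.

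In kidney medulla at 14 and 42 kBq Angptl4 rose 3.17-fold and 2.82-fold, Pdk4, a switch from glucose to fat oxidation, 2.48-fold and 2.65-fold, and Per1 1.78-fold and 2.25-fold. Fcrls fell by 1.97 and 2.10, and the matrix gene Lum by 1.02 and 1.56. At 42 kBq 4 of 12 glucocorticoid and fasting responsive genes rose over all probes and 6 when adjusted over the list alone (adjusted p = 3.57e-06, adjusted p = 0.0158 with an estimated correlation). Fibroblast and matrix genes fell, 5 of 15 with 1 rise over all probes, and 6 with 1 rise when adjusted over the list alone (adjusted p = 0.000825, adjusted p = 0.245 with an estimated correlation). Cdkn1a rose 1.65-fold and Mdm2, a p53 target, 1.35-fold at 42 kBq, on 1 of its 3 probes. There were 33 rises and 34 falls at 14 kBq, and 315 and 457 at 42 kBq. With the replicate number as a block 149 were called at 14 kBq. With 1 of the 6 arrays left out 23 to 30 were called at 14 kBq, except 81 without array 3 of 14 kBq, and 378 to 416 at 42 kBq.

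**Figure D3:**
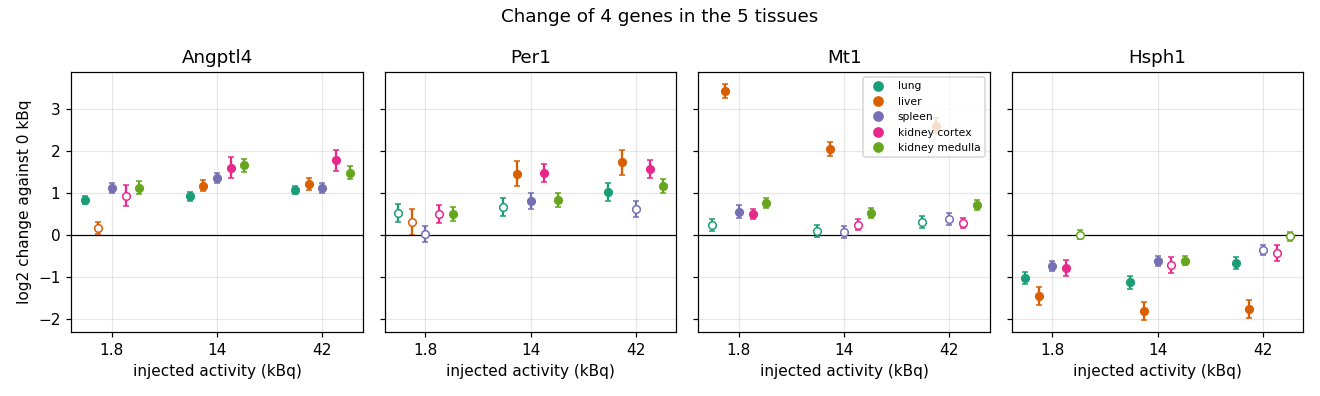
Change against 0 kBq (log2, with SE) of 4 genes at 1.8, 14 and 42 kBq, coloured by tissue. Filled points passed the test. Angptl4 passed it in 13 of 15 combinations and Hsph1 in 10.

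Some genes moved alike in several tissues at 1.8, 14 and 42 kBq, which makes 15 combinations of tissue and activity. Angptl4 rose in 13, Per1 in 9, Txnip in 9, Cirbp in 8 and Mt1 in 8. The heat shock genes Hsph1 and Fkbp4 fell in 10 and 8. Fcrls was tested in 9 combinations and fell in 8. Of the p53 targets Cdkn1a rose in 3 and Mdm2 in 2, and Ccng1 and Phlda3 in 0. Both Mdm2 calls, in kidney medulla at 1.8 and 42 kBq, rested on 1 of 3 probes, and the others had changes of 0.08 and -0.11, and of 0.22 and 0.10. For Cdkn1a 1 of 2 other probes was called in kidney cortex at 1.8 kBq and 0 of 2 in kidney medulla at 42 kBq. Other probes of the same gene were also not called for Per1 in lung at 42 kBq and for 0.64 against 0.064 kBq, in liver at 14 kBq, and in kidney medulla at 1.8 and 14 kBq. The same held in lung at 14 kBq for Scgb3a1 and Oas1g, in liver at 1.8 kBq for Dio1, in liver at 42 kBq for 1 of 2 of Usp2, in spleen at 14 kBq for Tsc22d3, and in kidney cortex at 14 kBq for Slc22a13 and 1 of 2 of Napsa. Of the clock genes Dbp, Per2 and Nr1d1 were called in 0, and Arntl fell in 1. Among 11851 probes tested in all tissues, 27 rose and 11 fell in at least 3 tissues at 1.8 kBq, where shuffling probes gave means of 1.03 and 0.74. At 14 kBq these were 4 and 5, and at 42 kBq 9 and 2. The activities of a tissue share its control arrays. Shuffling treats the tissues as independent, although array 1 of 0.64 kBq was male-type in all 5, as tissues of 1 animal would be, so sharing through the animals is not accounted for.

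The comparison of 0.64 with 0.064 kBq lay within set 2. Its tests used a variance pooled over all groups of a tissue, most of them in set 1. Arrays of set 1 spread less within groups (median probe SD 0.153 against 0.213 in set 2). The p-values given here may thus be too small. In liver Per1 rose 4.18-fold (8.84 ± 0.24 against 6.78 ± 1.02, SD, n = 3, adjusted p = 0.000507, limma). Of 16 acute phase genes 6 rose over all probes and 8 when adjusted over the list alone (adjusted p = 0.000121, adjusted p = 0.38 with an estimated correlation), Lcn2 4.62-fold. Of 14 cholesterol synthesis genes 8 fell over all probes and 10 when adjusted over the list alone (adjusted p = 2.29e-11, adjusted p = 0.352 with an estimated correlation), Nsdhl by 2.16. In kidney cortex 1 of 14 cholesterol synthesis genes fell over all probes and 4 when adjusted over the list alone (adjusted p = 8.96e-06, adjusted p = 0.0342 with an estimated correlation). In all, 11 lists were called in lung, 6 in liver, 3 in spleen, 8 in kidney cortex and 13 in kidney medulla, and with an estimated correlation only that kidney cortex list. Per1 also rose in lung (2.1-fold) and kidney medulla (1.87-fold), and in medulla Ucp1, a gene of brown fat, fell by 3.25. In spleen the granule gene Prtn3 rose 4.49-fold. There were 5 rises and 21 falls in lung, 282 and 396 in liver, 64 and 135 in spleen, 8 and 8 in kidney cortex, and 48 and 130 in kidney medulla. Array 1 of 0.64 kBq was male-type in Eif2s3y and Xist in all 5 tissues, unlike the other 85 arrays. Without it 192 were called in lung, 43 in spleen and 75 in kidney cortex. Over the 6 arrays left out in turn the calls ranged from 2 to 192 in lung, 231 to 2236 in liver, 13 to 754 in spleen, 14 to 76 in kidney cortex and 96 to 375 in kidney medulla. Fitted on these 6 arrays alone, limma called 0 in lung, liver, spleen and kidney cortex and 8 in kidney medulla. Nearly all calls of this comparison thus depend on the fit with the set 1 arrays. The fit on 6 arrays also had fewer residual degrees of freedom, and how much each of these mattered was not tested.

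Against 0 kBq, the 0.064 and 0.64 kBq arrays differed in 26.4% to 46.7% of the probes, and array set and activity cannot be told apart there. Calls at 0.064 and 0.64 kBq numbered 5432 and 4831 in lung, 4248 and 4798 in liver, 5995 and 6285 in spleen, 3982 and 4487 in kidney cortex, and 7145 and 7054 in kidney medulla. In kidney cortex at 0.064 kBq 2534 were called without array 3 of 0 kBq. In spleen the eosinophil gene Ear6 was at least 32.9-fold and 32.6-fold lower, and Prg2 had log2 changes of -4.80 and -4.84. In liver Dmbt1 was at least 28.5-fold lower at 0.064 kBq and had a change of -4.24 at 0.64 kBq, and Igfbp1 had 3.88 and 3.67. In kidney medulla Ucp1 was at least 48.9-fold higher at 0.064 kBq, Car3 at least 29.9-fold and 9.36-fold, and Slpi had changes of -4.94 and -4.62. The contrast of all injected groups with 0 kBq called 1361, 1348, 3132, 711 and 4160 probes in lung, liver, spleen, kidney cortex and kidney medulla. With 1 array left out these ranged from 197 to 2146, 407 to 1792, 1522 to 3591, 105 to 1086 and 2494 to 4504, the fewest in each tissue without array 2 of 0 kBq. With 1.8, 14 and 42 kBq alone these were 58, 392, 395, 165 and 1810. The slope over activity called 6625, 5971, 7185, 6156 and 8590, and over 1.8, 14 and 42 kBq alone 226, 740, 130, 749 and 1956. Over all 5 activities 51, 42, 47, 53 and 26 pairs of list and activity were called, and 4, 3, 3, 3 and 1 with an estimated correlation. The 1 of them at 0.064 or 0.64 kBq was the glucocorticoid and fasting list in liver at 0.64 kBq (adjusted p = 8.08e-05, adjusted p = 0.0449 with an estimated correlation).

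The response differed between kidney cortex and kidney medulla for 425 of 18463 probes, higher in medulla for 181 and lower for 244, and among the 5 tissues for 3062. Without array 1, 2 or 3 of the 0 kBq groups these were 141, 133 and 235, and 1762, 1138 and 1357. With 1.8, 14 and 42 kBq alone they were 347 and 1374. The marker lists did not tell the zones apart, so the comparison rests on the labels. At those activities Havcr1 had a mean change of 2.62 in cortex and -0.63 in medulla (adjusted p of the difference 2.12e-07, limma), Spink6 2.29 and -0.89 (adjusted p = 1.82e-09), and Ulk4 -0.24 and 1.74 (adjusted p = 0.000447). The zones started from unlike levels: in the fits given above, Havcr1 at 0 kBq was far higher in medulla than in cortex. At 1.8 kBq its mean in cortex was still below that in medulla. The opposite changes thus depend on the 3 control arrays of each zone, and whether the zones were sampled alike in every group was not tested.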

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

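The tests of the array sets, of growth with activity and of the order of the pancreas genes were chosen only after their results were seen. The islet test and the tests of RNA pools and of array noise were written down before their results, after the patterns had been seen. The noise test was to be decided by its median alone, and only after its value was seen was its upper quartile also required to lie under the bound. The bounds for the counts of regrouped arrays were also written down after those counts, although the regrouping itself had been planned. All tests of patterns rest on the same data in which the patterns were found.

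The effect of injection differed between kidney cortex and kidney medulla in a direct test for 425 probes, and among the 5 tissues for 3062, or 347 and 1374 with 1.8, 14 and 42 kBq alone. Without array 1, 2 or 3 of the 0 kBq groups the counts were 141, 133 and 235, and 1762, 1138 and 1357. The medulla minus cortex differences (log2, pooled over the activities) were 2.32 for Ulk4, 1.64 for Necab1, 1.32 for Spon2, 1.27 for S100a9 and 1.27 for Pcyt1a. On the other side they were -2.32 for Havcr1, -2.31 for Spink6, -2.21 for Slc22a19, -2.17 for Serpina1f and -2.10 for Mep1b. Among the 5 tissues the pooled differences of fitted levels were in spleen for Cela2a (5.49), Clps (5.36), Amy2a5 (5.31), Try10 (5.23) and Try5 (5.05). They were in liver for Dmbt1 (-4.55), Serpina4-ps1 (-3.36) and Ccl8 (-2.92), in lung for Cxcl9 (-2.81) and in kidney medulla for Slpi (-2.62). In spleen Dmbt1 and Ccl8 had pooled differences of the other sign, 4.06 and 1.14, and whether pancreatic tissue contributed to these was not tested. The 5 spleen genes were undetected at 0 kBq, and Dmbt1 and Ccl8 were undetected in liver at 1.8 and 42 kBq, so these values depend on the background level and are no bounds or ranks. As many calls came from 2 of 100 splits for the kidney zones (highest other 438) and from 1 of 100 for the 5 tissues (highest other 934), both under a share of 0.05. These splits mixed both array sets and were drawn separately in each tissue. A set difference that varies by tissue, or animals shared between tissues, could give such counts, so the share does not settle whether the effect of activity differs. No splits were run with 1.8, 14 and 42 kBq alone.

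The first pattern is the expression difference between the 0.064 and 0.64 kBq arrays and all others. As the source of this difference, a response that grows with injected activity is argued against. For probes called alike at 0.064 and 0.64 kBq, the change at 42 kBq was set against that at 0.64 kBq. The median ratio was at most 0.140 in any tissue. These probes were picked by their change at 0.64 kBq, so a smaller growing response beside the difference is not addressed. The contrast of the sets was shared by all tissues, with a median correlation across probes of 0.71 between tissues, where genes are not independent replicates. Within a set no comparison exceeded 0.46. Separate handling of the sets is a candidate explanation, and animals or a response confined to low activities stay open, since every group lies in 1 set.

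The second pattern is pancreatic transcripts on the spleen arrays of 1.8, 14 and 42 kBq. A response that grows with activity is argued against, since the list mean at 14 kBq was -4.26 from that at 1.8 kBq. Pancreatic tissue taken with the spleen may account for it: all 20 list genes changed more at 1.8 than at 14 kBq, but any shared rise would do the same, and 2 of the 20 were detected on a 0 kBq spleen array. The test of whole pancreas did not settle it, since 1 of 6 islet genes met its bound of 2: Ins2 was at least 4.73-fold higher at 1.8 kBq, Iapp was undetected at 0 and 1.8 kBq, and 4 were not tested. Carried-over tissue therefore stays open as a hypothesis.

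The third pattern is near-equal marker levels among the 3 arrays of a group in set 1, in 9 pairs of tissue and list picked after their values were seen, with a spread within groups of a median of 0.0837 of that in set 2, although 1 of the 9, tubular injury in kidney medulla, had 1.69. In the other 174 pairs the median ratio was 0.325, with 121 under 0.5 and 12 at 1 or more. Divided by that of random gene sets of equal size and level, the ratio had a median of 0.461 with quartiles of 0.262 and 0.775, so the median met its bound of 0.5, which by itself would argue against lower array noise alone, but by less than this spread, and that explanation stays open. Arrays of a group that hold 1 RNA pool are a candidate explanation, and more uniform animals in set 1 were not tested. The 0.064 kBq group of set 2 holds no male-type array. In lung its SDs were 0.65, 0.72, 0.55 and 0.31 for airway, cardiac muscle, skeletal muscle and neutrophil lists. They were 0.70 for liver neutrophil, 0.33 for kidney medulla adipose and 0.25 for kidney cortex tubular injury lists. Pooled over the groups of set 1, the SD of a list was at most 0.079. The highest SD of a single set 1 group was 0.12, for kidney medulla adipose at 42 kBq. For these lists this argues against the male-type array. The spleen pancreas list had 0.01 and kidney medulla tubular injury 0.05. There and in the other 174 pairs that array was not tested. With pools, the p-values at 1.8, 14 and 42 kBq would leave out the spread between animals.

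Other splits of the arrays were counted for each comparison. The splits regroup arrays, so they do not exclude chance between animals where the arrays of a group hold the same RNA, which was not settled. For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. In all 25 comparisons with 0 kBq 1 of 10 splits gave as many calls, the real one, and the highest other was 0 except 3 in lung at 0.64 kBq. The real values ran from 18 in kidney cortex at 14 kBq to 7145 in kidney medulla at 0.064 kBq. For 0.64 against 0.064 kBq the real values and highest others were 26 and 258 in lung (6 of 10 as high), 678 and 445 in liver (1), 199 and 561 in spleen (2), 16 and 257 in kidney cortex (5) and 178 and 169 in kidney medulla (1). The highest splits mixed the groups and put array 1 of 0.64 with array 1 of 0.064 kBq, which points to a structure of these samples. In 5 comparisons same-numbered arrays deviated together, and there the real count was set beside the 3 other splits that also part all 3 same-numbered pairs. These gave at most 3 calls in lung and 58 in kidney cortex for 0.64 against 0.064 kBq (real values 26 and 16). They gave 0 in spleen at 14 and 42 kBq and in kidney cortex at 1.8 kBq. The remaining 6 splits each keep 2 same-numbered pairs together, 1 on each side.

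For all activities against 0 kBq, the splits with as many calls of 100 were 3 in lung (1361, highest other 2388), 2 in spleen (3132 and 3361), 1 in kidney cortex (711 and 4) and 2 in kidney medulla (4160 and 4370), which excludes chance at 0.05. In liver they were 5 (1348 and 2642), which does not. For the slope they were 1 in each tissue, with highest others of 3815, 283, 1323, 1100 and 367 in lung, liver, spleen, kidney cortex and kidney medulla. This excludes chance among regrouped arrays, but set 2 holds the lowest injected activities, so a set difference alone could give such counts. With 1.8, 14 and 42 kBq alone the slope called 226, 740, 130, 749 and 1956 probes, and no splits were run there. For called lists the splits with as many calls were 4 in liver (42 and 60) and 2 in kidney cortex (53 and 66), which excludes chance. They were 5 in lung (51 and 65), 6 in spleen (47 and 58) and 30 in kidney medulla (26 and 69), which does not. All activities against 0 kBq and the called lists also include set 2, so there too the splits do not part activity from array set. Wherever chance is excluded here, this refers to regrouped arrays and not to chance between animals.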

How the results depend on the processing

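The tests in this part that leave out the 0.064 and 0.64 kBq arrays or use 1.8, 14 and 42 kBq alone were chosen only after the results were seen. The values in this part are numbers of probes called, or of pairs of list and activity. Changes of over 1.5 times in a count are listed, and the cause was not tested unless said. No result reversed: none of the 282 named values changed sign where it passed the test in either fit. Of the 282, 267 kept their side of the threshold with the deposited table, 274 without background correction, 274 without a filter on dim probes, 280 with normalization over all 90 arrays, 279 with the replicate block, 207 at the stricter threshold and 242 on the 6 arrays alone. Without the 0.064 and 0.64 kBq arrays 242 of 250 did, and 8 newly passed. With 1 array left out 1326 of 1686 did, and 357 no longer passed. All 42 counts without background correction and all 45 with normalization over all 90 arrays stayed within 1.5 times. In kidney cortex at 14 kBq 12 probes rose and 6 fell without background correction, against 14 and 4 with it. Chip as a block was not run because no chip was named. The deposited table was not run for comparisons across array sets, lists and differences between tissues, because its sets were on different scales. Signal over background limited the tests to 53.2% to 62.5% of the probes.

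With a threshold of adjusted p under 0.01 and at least 1.5-fold, which by construction calls fewer, 39 of 40 counts moved. The counts were in lung 2715 for 0.064 kBq, 2168 for 0.64 kBq, 16 for 1.8 kBq, 34 for 14 kBq, 69 for 42 kBq, 2 for 0.64 against 0.064 kBq, 208 for all activities and 135 for the slope. In liver there were 2224 for 0.064 kBq, 2647 for 0.64 kBq, 148 for 1.8 kBq, 70 for 14 kBq, 186 for 42 kBq, 120 for 0.64 against 0.064 kBq, 305 for all activities and 323 for the slope. In spleen they were 3444 for 0.064 kBq, 3696 for 0.64 kBq, 179 for 1.8 kBq, 122 for 14 kBq, 5 for 0.64 against 0.064 kBq, 859 for all activities and 439 for the slope. In kidney cortex there were 1729 for 0.064 kBq, 2248 for 0.64 kBq, 98 for 1.8 kBq, 3 for 14 kBq, 135 for 42 kBq, 5 for 0.64 against 0.064 kBq, 131 for all activities and 331 for the slope. In kidney medulla they were 3923 for 0.064 kBq, 3878 for 0.64 kBq, 1567 for 1.8 kBq, 21 for 14 kBq, 188 for 42 kBq, 63 for 0.64 against 0.064 kBq, 940 for all activities and 510 for the slope. At that threshold the difference between kidney zones had 168 calls, and at adjusted p under 0.01 that among the 5 tissues had 1535. With an estimated inter-gene correlation the called pairs of list and activity were 4 in lung, 3 in liver, 3 in spleen, 3 in kidney cortex and 1 in kidney medulla.

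Fitted on the 6 arrays of a comparison alone, 21 of 30 counts moved. The counts were in lung 2884 for 0.64 kBq, 467 for 1.8 kBq, 752 for 14 kBq, 233 for 42 kBq and 0 for 0.64 against 0.064 kBq. In liver there were 1732 for 1.8 kBq, 1194 for 14 kBq, 1447 for 42 kBq and 0 for 0.64 against 0.064 kBq. In spleen they were 825 for 1.8 kBq, 1618 for 14 kBq, 359 for 42 kBq and 0 for 0.64 against 0.064 kBq. In kidney cortex there were 2546 for 0.064 kBq, 739 for 1.8 kBq, 450 for 14 kBq, 905 for 42 kBq and 0 for 0.64 against 0.064 kBq. In kidney medulla they were 331 for 14 kBq, 1411 for 42 kBq and 8 for 0.64 against 0.064 kBq. Without the 0.064 and 0.64 kBq arrays 14 of 15 counts rose by over 1.5 times; those arrays spread more within groups (median probe SD 0.213 against 0.153). The counts were in lung 615 for 1.8 kBq, 916 for 14 kBq and 347 for 42 kBq. In liver there were 1876 for 1.8 kBq, 1013 for 14 kBq and 1596 for 42 kBq. In spleen they were 1275 for 1.8 kBq, 1636 for 14 kBq and 257 for 42 kBq. In kidney cortex there were 1293 for 1.8 kBq, 396 for 14 kBq and 800 for 42 kBq. In kidney medulla they were 369 for 14 kBq and 1524 for 42 kBq. With 1.8, 14 and 42 kBq alone 11 of 12 counts moved. They were in lung 58 for all activities and 226 for the slope. In liver there were 392 for all activities and 740 for the slope. In spleen they were 395 for all activities and 130 for the slope. In kidney cortex there were 165 for all activities and 749 for the slope. In kidney medulla they were 1810 for all activities and 1956 for the slope. The difference among the 5 tissues had 1374. Without a filter on dim probes 0.64 against 0.064 kBq had 6 calls in lung and 127 in spleen, and with the deposited table it had 51 in lung.

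The replicate number as a block moved 1 of 47 results by over 1.5 times: kidney medulla at 14 kBq had 149 calls with the block, and no other count crossed that bound. In 11 of the 30 comparisons every array correlated best with its own number, a hint from the data and not the design. The correlations of same-numbered arrays ran from -0.19 to 0.41, with a median of 0.08.

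With 1 array left out at a time, 113 of 366 counts moved. Of the 366, 307 were lower and 59 higher than with all arrays, and the cause was not tested. The lowest and highest counts follow, and the array whose absence gave the lowest stands beside it. In lung they were 9 to 140 for 1.8 kBq (0 kBq array 2), 20 to 100 for 14 kBq (14 kBq array 2), 64 to 81 for 42 kBq (42 kBq array 1), 197 to 2146 for all activities (0 kBq array 2) and 2 to 192 for 0.64 against 0.064 kBq (0.064 kBq array 2). In liver they were 194 to 274 for 1.8 kBq (0 kBq array 3), 67 to 98 for 14 kBq (14 kBq array 3), 237 to 309 for 42 kBq (42 kBq array 2), 407 to 1792 for all activities (0 kBq array 2) and 231 to 2236 for 0.64 against 0.064 kBq (0.64 kBq array 2). In spleen they were 207 to 287 for 1.8 kBq (0 kBq array 2), 129 to 244 for 14 kBq (0 kBq array 2), 1522 to 3591 for all activities (0 kBq array 2) and 13 to 754 for 0.64 against 0.064 kBq (0.064 kBq array 2). In kidney cortex they were 2534 to 4012 for 0.064 kBq (0 kBq array 3), 103 to 192 for 1.8 kBq (1.8 kBq array 1), 2 to 5 for 14 kBq (0 kBq array 1), 137 to 168 for 42 kBq (42 kBq array 3), 105 to 1086 for all activities (0 kBq array 2) and 14 to 76 for 0.64 against 0.064 kBq (0.64 kBq array 2). In kidney medulla they were 23 to 81 for 14 kBq (0 kBq array 3), 378 to 416 for 42 kBq (42 kBq array 3), 2494 to 4504 for all activities (0 kBq array 2) and 96 to 375 for 0.64 against 0.064 kBq (0.64 kBq array 2). Without array 1, 2 or 3 of all 0 kBq groups the difference between kidney zones had 141, 133 and 235 calls and that among the 5 tissues 1762, 1138 and 1357.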

Other observations

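Array 1 of the 0.64 kBq group stood apart in sex-linked genes in all 5 tissues. The Y-linked gene Eif2s3y was detected on these 5 arrays, at 7.81 to 8.89, and on 0 of the other 85, at 4.29 to 4.75. Both probes of Xist, the transcript of the inactive X chromosome, were undetected on the 5 arrays, at 4.56 to 5.45, and detected on all 85 others, at 6.33 to 9.47 and 6.37 to 9.17. Without that array the count of probes called for 0.64 against 0.064 kBq in lung was 192, against 26 with it.

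Fat cell genes varied within set 2 on kidney medulla arrays. The mean of the adipose list was 8.86 at 0.064 kBq, from 8.61 to 9.23, and 7.20 at 0.64 kBq, from 5.33 to 9.16, against 5.02 at 0 kBq and 6.48 at 1.8 kBq. In lung the neutrophil and granule list had means of 9.38 at 0 kBq, 8.35 at 14 kBq and 9.77 at 42 kBq, and of 7.79 and 7.93 at 0.064 and 0.64 kBq. Oas1g fell at 14 kBq in lung, spleen and kidney medulla, by at least 6.25-fold, 7.17-fold and 2.61-fold. It was called in 3 of 15 combinations of tissue and activity.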
